A study of Bos taurus with 11 samples.

How the data were processed

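Gene expression was measured on 1-colour arrays hybridised with biotin-labelled RNA from mammary parenchyma, the epithelial tree and its supporting tissue, of 11 female Holstein calves. Per the labels, calves were allotted at birth to an elevated or a restricted supply of milk replacer, 6 calves each, and were killed at 54 ± 2 days. The parenchyma of 1 restricted calf was too small to part from the fat pad and was not sampled, so 6 elevated and 5 restricted calves have arrays. The restricted group therefore lacks the calf with the least developed gland, a loss that is not random with respect to the outcome. RNA was taken forward only at an integrity number above 7.0, and 100 ng per sample was labelled, per the labels' protocols.

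The values deposited by the authors are RMA values per probe set on a log2 scale. RMA is named in the submitters' processing notes with no version, and its background, array definition and summarisation settings are not given in the sources used here. The log2 scale itself was read from the values, which start at 1.082 and have array medians between 6.368 and 6.455. A gap of 1 on this scale is a 2-fold difference in signal, and RMA compresses differences of dim probe sets. RMA also gives all arrays nearly the same distribution, so a change in total RNA per cell cannot appear. No 2 arrays held the same values, and correlations between arrays ran from 0.964 to 0.990. The number of arrays, not a read depth, limits the precision.

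The table held 26773 probe sets. By the platform annotation, 18790 had exactly 1 gene symbol, 385 had several and 7598 had none here. Symbols were looked up again by gene number in a reference gene table of the assembly ARS-UCD2.0; 18003 of the probe sets with 1 symbol were found, and 0 symbols changed. No coordinates are given because the array's genome build is not named in the sources used here. A gene with several probe sets (320 of 18444 genes) was represented by the one with the highest mean over all 11 arrays.

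The following choices were made before the data were examined, except where stated. The main test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values as deposited, no filter and no covariate, and Benjamini-Hochberg adjustment over all probe sets at a threshold of 0.05. Changes are elevated minus restricted. SE is the moderated standard error, and intervals are at the 95% level. The labels describe the arrays as coming from different calves, so the spread is between animals.

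Genes named in the text followed a rule. The first part took up to 12 genes per direction past the threshold with no overlap between the groups, filled up with the smallest unadjusted p where fewer qualified. The second took up to 4 members of each gene list with the smallest p. The third was a set of 18 genes always given. Probe sets with several symbols and uncharacterised loci were left out. Genes named outside the rule are marked as chosen after their values were seen.

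The gene lists, 28 in all, were fixed from textbook knowledge of the mammary gland, of nutrient responses and of other cell types that the sample could hold. They had 9 to 84 measured members. Each was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists. An exact two-sided permutation test of the list's mean per calf, over all 462 splits of the calves into 6 and 5, stands beside it. Camera asks whether a list moved relative to all other genes, and at a preset correlation it takes list members as nearly independent; the permutation test uses calves as the unit. Alternatives were camera with an estimated correlation and limma's fry.

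Other alternatives were quantile normalisation, median centring, filters on dim probe sets and on probe sets without a gene, other variance models, array weights, Welch's test, other thresholds, the replicate number as a block, marker means as covariates, the mean over a gene's probe sets, and leaving out each calf. Fits without restricted 2, restricted 4 and elevated 5 were added after seeing the data. The tests were checked on simulated data with the real spread of this comparison over 26773 probe sets. They recovered 50.7% of 67 probe sets changed 1.5-fold, 83.6% of 67 changed 2-fold and 90.9% of 66 changed 4-fold. Of 157 calls, 7 were false, and 0 calls were made with none changed. The simulated genes were independent, so this check says nothing of camera on lists whose members move together. Nor does it cover the number of false calls where many probe sets move together across calves. Calves are named by group and by the number in their titles. Figures were drawn with matplotlib 3.10.9.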

Results

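Array profiles of mammary parenchyma were compared between calves on 2 planes of milk replacer before weaning. Elevated calves (n = 6) took a mean of 5.9 ± 0.2 (SE) Mcal of metabolisable energy per day in 8.4 L of milk replacer. Restricted calves (n = 5) took 2.8 ± 0.2 Mcal per day in 4 L. Both groups had access to starter grain from day 18. The labels give elevated calves 3 meals and 6 to 12 L per day, and restricted calves 2 meals per day. Meal number therefore went with the amount supplied and cannot be told apart from it. The comparison asks how nutrient supply before weaning, meal number included, alters transcript levels in the gland. On each array 26773 probe sets were read. A principal component with 26% of the variance was carried by restricted 2 (score 62.3) and did not part the diets (exact permutation p = 0.387). The next, with 21.4%, did part them (exact permutation p = 0.00649), and elevated 5 had its most extreme score (64.5).

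FMN1, which encodes the actin-nucleating protein formin-1, was the named gene that changed past the threshold, and it fell in elevated calves. Its log2 level was 7.52 ± 0.23 (SD, n = 6) in elevated and 8.68 ± 0.17 (SD, n = 5) in restricted calves, a log2 change of -1.16 ± 0.12 (SE; limma adjusted p = 0.0228). Every elevated calf lay below every restricted calf. An unnamed probe set, 12852810, fell by 1.80 on the log2 scale (SE 0.21; adjusted p = 0.0303), likewise with no overlap between the groups. In all, 0 probe sets rose and 2 fell at an adjusted p under 0.05 in limma. At an unadjusted p under 0.05 there were 2750 (1324 higher, 1426 lower), against 1339 by chance. The groups did not overlap at 343 probe sets (1.28%), where chance gives 0.433% on average. Probe sets that move together across calves can raise this count, and it was not tested by regrouping the calves. Both calls were sensitive to single animals. The count was 0 without elevated 1, elevated 3, restricted 1 or restricted 5, 1 without elevated 6, 8 without restricted 2 and 12 without elevated 4. An unmoderated test per probe set with the same adjustment gave 0. Without restricted 2 and restricted 4, which stood apart in their adipocyte markers and were left out after seeing the data, the count was 25, of which 3 were higher and 22 lower in elevated calves.

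Among genes measured higher in elevated calves, none passed the adjustment over all probe sets. CSN2, which encodes the milk protein beta-casein, stood first. It averaged 6.72 ± 0.65 (SD) in elevated and 4.53 ± 0.44 in restricted calves, a log2 difference of 2.19 ± 0.31 (SE; adjusted p = 0.1004), and all elevated calves lay above all restricted calves. ABCC8, a subunit of ATP-sensitive potassium channels, averaged 2.14-fold higher, and the tetraspanin gene TSPAN2 2.41-fold higher. The other genes with the smallest p were CAMK1D (0.90), ZSWIM5 (0.83), RGS4 (1.12), JUN (0.67), PLD5 (1.81), the amino acid transporter gene SLC6A15 (1.32), SLITRK6 (1.51), the cyclic AMP phosphodiesterase gene PDE8B (0.54) and ZBTB7B (0.43), each as a log2 difference. Values of ZSWIM5 and SLC6A15 overlapped between the groups, and those of the others did not. CSN2 passed the threshold when elevated 2 was left out, and ABCC8 and TSPAN2 when elevated 4 was left out.

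Among genes measured lower in elevated calves, PLOD2 came next after FMN1. PLOD2 encodes a lysyl hydroxylase that prepares collagen for cross-linking. It averaged 8.06 ± 0.37 (SD) in elevated and 9.18 ± 0.10 in restricted calves (log2 difference -1.13 ± 0.16 SE; adjusted p = 0.1004). DDC, the decarboxylase that makes dopamine and serotonin, differed by -1.60. The lymphatic growth factor gene VEGFC differed by -0.84, and RDH10, which acts in retinoic acid synthesis, by -0.59. The remaining log2 differences were -0.55 for C18H16orf87, -0.76 for RNF152, -1.07 for KHDRBS2, -0.86 for TTLL7, -0.89 for FOLH1, -1.05 for FGL1 and -0.77 for GPR155. FOLH1 overlapped between the groups, and the others did not. None of these passed the adjustment over all probe sets.

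**Figure D1:**
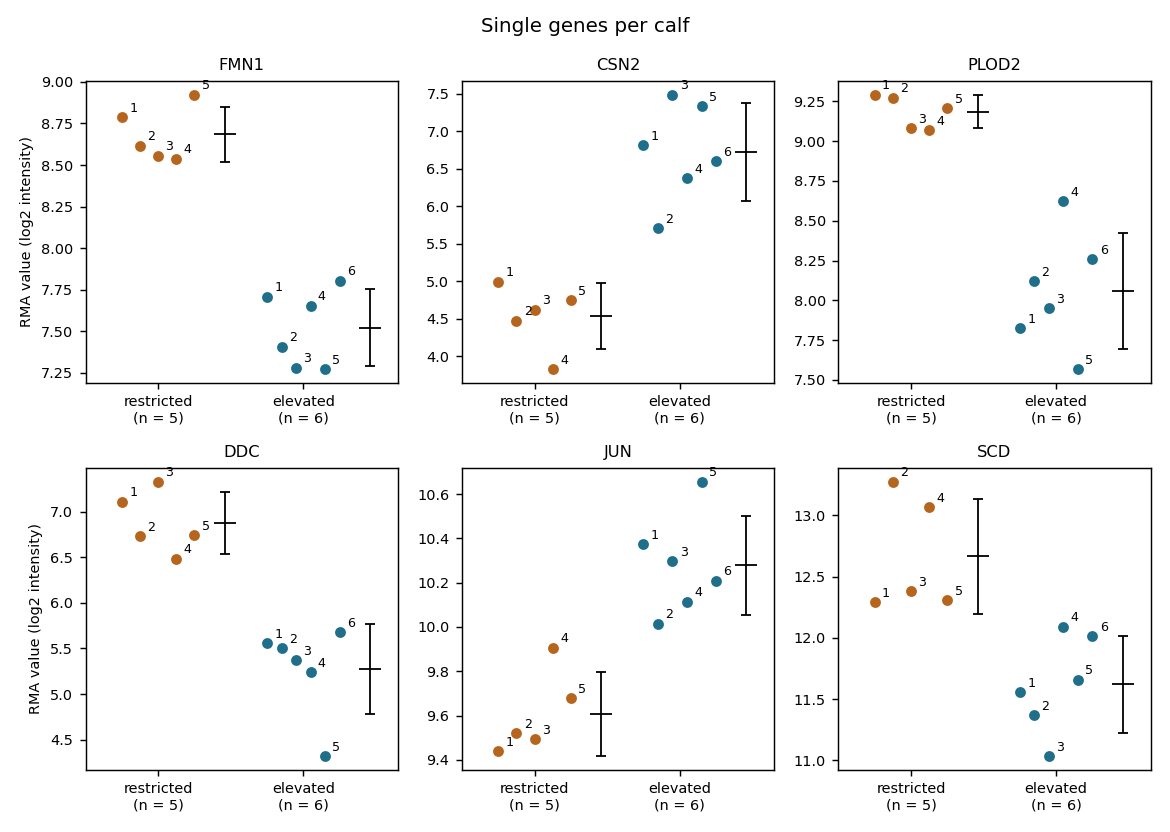
RMA values (y axis, log2 intensity) of 6 genes in each restricted (n = 5) and elevated (n = 6) calf; points carry the calf's number, and the bar with whiskers is the group mean ± SD. FMN1, PLOD2, DDC and SCD lie lower and CSN2 and JUN higher in every elevated calf than in any restricted calf, and of these FMN1 alone passed the adjusted threshold (adjusted p = 0.0228).

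Gene lists were then tested as groups. Of the 28 lists, 10 passed camera at its preset correlation, 4 as higher and 6 as lower in elevated calves. With an estimated correlation 0 passed (smallest adjusted p = 0.753). By the exact permutation test over calves, 3 lists had an unadjusted p under 0.05 and 0 passed after adjustment over the lists (smallest adjusted p = 0.303). Over all probe sets 0 list members passed, and adjusted over the list alone 18 did, each named with its list below.

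Lipid genes were lower in elevated calves. The list for fatty acid and triglyceride synthesis averaged 9.14 ± 0.18 (SD, n = 6) in elevated and 9.77 ± 0.57 (SD, n = 5) in restricted calves, a mean log2 difference of -0.63. All 22 measured members were lower (camera adjusted p = 2.3e-09; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0108, 0.303 adjusted). SCD, the desaturase that makes oleic acid (-1.04 ± 0.24 SE), and THRSP, a regulator of lipogenesis (-1.99 ± 0.56 SE), were the 2 members past the threshold adjusted over the list alone. FASN, the fatty acid synthase, differed by -0.86 and GPAM, which starts glycerolipid synthesis, by -1.23. The adipocyte marker list differed by -0.90, with 24 of 26 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0844). Its members LEP, the gene of the adipose hormone leptin, DGAT2, AQP7 and ADIPOQ differed by -1.65, -1.63, -1.40 and -0.92. Restricted 2 and restricted 4 had adipocyte means of 10.15 and 9.62, while the other 9 calves lay between 7.28 and 8.68. The adipocyte list differed by -0.58 without restricted 2. Without both calves it differed by -0.24 and lost its call (camera adjusted p = 0.253). The fatty acid list differed by -0.23 and kept its call (camera adjusted p = 0.00476). The differences of these lists were alike in size, and camera at its preset correlation takes members as nearly independent. The kept call therefore does not set the fatty acid list apart from the adipocyte list.

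Luminal epithelial genes were higher in elevated calves. The luminal list averaged 8.86 ± 0.36 (SD, n = 6) against 8.15 ± 0.99 (SD, n = 5), a mean log2 difference of 0.71 with 26 of 27 members higher. Its camera adjusted p was 1.5e-08 (adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.102), and 0 members passed when adjusted over the list alone. KRT18, a keratin of luminal cells, differed by 1.00, FOXA1, a partner of the oestrogen receptor, by 1.12, PROM1 by 0.64, CLDN3 by 0.62 and the prolactin receptor gene PRLR by 1.05. Without restricted 2, KRT18, FOXA1 and PRLR differed by 0.62, 0.64 and 0.61. The luminal mean was 6.51 in restricted 2 and 7.91 in restricted 4, the calves with the highest adipocyte means, and at least 8.36 in each other calf. The difference was 0.30 without restricted 2, 0.088 without both (camera adjusted p = 0.175) and -0.053 with the adipocyte mean as a covariate (camera adjusted p = 0.937). The basal and myoepithelial list differed by 0.11 (camera adjusted p = 0.546), and its keratin KRT5 by 0.20. Without restricted 2 they differed by -0.15 and -0.36, and without both calves the basal list was called lower (-0.29, camera adjusted p = 0.0412).

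Milk protein genes did not pass as a list in the full comparison (mean log2 difference 0.24, camera adjusted p = 0.546; exact permutation p = 0.0346, 0.343 adjusted). With the dimmest probe sets left out, the members that remained differed by 0.59 and the list was called higher (camera adjusted p = 0.0372). With the adipocyte mean as a covariate the list differed by 0.079 (camera adjusted p = 0.823). Without restricted 2 and restricted 4 it differed by 0.14 (camera adjusted p = 0.912). Its 16 measured members split into 9 higher and 7 lower. Adjusted over the list alone, 2 were past the threshold, CSN2 and PIGR, the receptor that carries immunoglobulins across epithelium (log2 difference 2.09 ± 0.49 SE). LTF, the gene of the iron-binding milk protein lactoferrin, differed by 1.15 (0.60 without restricted 2) and LALBA by -0.0016, the latter at a level of 2.8 on the log2 scale. In the list of hormone and growth factor signalling, 20 of 43 members were higher (camera adjusted p = 0.546), with a mean difference of 0.097 (0.019 without restricted 2) and a median of -0.022. EGFR, at -0.45 ± 0.09 (SE), was the 1 member past the threshold adjusted over the list alone. Log2 differences were 0.46 for the oestrogen receptor gene ESR1 (0.26 without restricted 2), -0.60 for the progesterone receptor gene PGR (-1.07 without restricted 2), -0.15 for GHR, -0.16 for IGF1, 0.49 for IGF1R, -0.081 for IGFBP3 and 1.36 for TNFSF11, the gene of RANK ligand. GHR, IGF1 and IGFBP3 also moved by over 1.5 times when single calves were left out, and PGR differed by -0.36 without restricted 5.

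Immediate early genes, which are switched on within minutes of a stimulus and many of which code for transcription factors, were higher in elevated calves. The list differed by 0.30, with 20 of 25 members higher (camera adjusted p = 1.6e-05; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0368, 0.343 adjusted). JUN (0.67 ± 0.12 SE), FOS (1.37 ± 0.28 SE) and FOSB (1.00 ± 0.28 SE) were the 3 members past the threshold adjusted over the list alone. Skeletal muscle markers were also higher, by 0.49 with 21 of 24 members higher and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0714). The muscle list averaged 5.76 in elevated and 5.28 in restricted calves, under the array medians of 6.368 to 6.455. ACTA1 differed by 1.22, ACTN2 by 1.06 and MYL2 by 0.75. Elevated 5 had the highest means of both lists, 8.46 for immediate early genes and 6.73 for muscle markers; without this calf the muscle list differed by 0.29 and kept its call. Ribosomal protein genes were higher by 0.055, with 52 of 69 members higher and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0628). RPL8 differed by 0.23. The list lost its call without restricted 2 and restricted 4 (0.027, camera adjusted p = 0.144) and with the adipocyte mean as a covariate (0.028, camera adjusted p = 0.159).

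Matrix genes were lower in elevated calves. The list for fibrillar and basement membrane matrix differed by -0.17, with 32 of 48 members lower (camera adjusted p = 2.2e-04; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.0887). Adjusted over the list alone, 5 members were past the threshold: PLOD2, the laminin genes LAMB1 (-0.46 ± 0.09 SE), LAMC1 (-0.27 ± 0.07 SE) and LAMA2 (-0.49 ± 0.13 SE, named after its values were seen), and the basement membrane collagen gene COL18A1 (-0.59 ± 0.14 SE). Without restricted 2 and restricted 4 the list differed by -0.058 and lost its call, as it did with the adipocyte mean as a covariate (-0.019, camera adjusted p = 0.937). Lists of mitochondrial genes were also lower. Nuclear-encoded oxidative phosphorylation genes differed by -0.14, with 74 of 84 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.152), and COX8B and UQCRH by -1.13 and -0.28. The beta oxidation list differed by -0.21, with 17 of 22 lower (camera adjusted p = 0.0058; adjusted p = 0.753 with an estimated correlation; exact permutation p = 0.193). Its 2 members past the threshold adjusted over the list alone went opposite ways, BDH1 of ketone body metabolism at -1.39 ± 0.38 (SE) and ECI2 at 0.39 ± 0.10 (SE). Without restricted 2 the mitochondrial lists differed by -0.055 and -0.082, and both lost their calls; COX8B and UQCRH differed by -0.63 and -0.18. With all calves kept, both lists also lost their calls with array weights (-0.056 and -0.11; camera adjusted p = 0.1205 and 0.133) and with the adipocyte covariate (-0.011 and 0.049; camera adjusted p = 0.937 and 0.617).

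Cell division genes were lower on average in elevated calves, in a direction that hung on which calves were included. All 41 measured mitosis genes had lower means (list difference -0.32, camera adjusted p = 0.0056; adjusted p = 0.871 with an estimated correlation; exact permutation p = 0.816), and 0 passed when adjusted over the list alone. The proliferation marker MKI67 differed by -0.30, TOP2A by -0.51 and CENPA by -0.55. The mitosis mean of elevated 5 was 5.91, against 7.91 to 8.55 in the other 10 calves. Without elevated 5 the list difference was 0.078, called in the opposite direction (camera adjusted p = 0.0336), and MKI67, TOP2A and CENPA differed by 0.19, 0.020 and -0.12. Without restricted 2, restricted 4 and elevated 5, left out after seeing the data, the list differed by -0.097 and was called lower (camera adjusted p = 0.00457). With array weights and all calves it differed by -0.13 and lost its call (camera adjusted p = 0.142), and with the adipocyte mean as a covariate it differed by -0.66 and kept it (camera adjusted p = 7.7e-08). The DNA replication list differed by -0.054, with 27 of 46 members lower (camera adjusted p = 0.719). Without elevated 5 it differed by 0.11 and was called higher (camera adjusted p = 6.6e-04), and with the adipocyte covariate by -0.21 and was called lower (camera adjusted p = 0.0014).

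**Figure D2:**
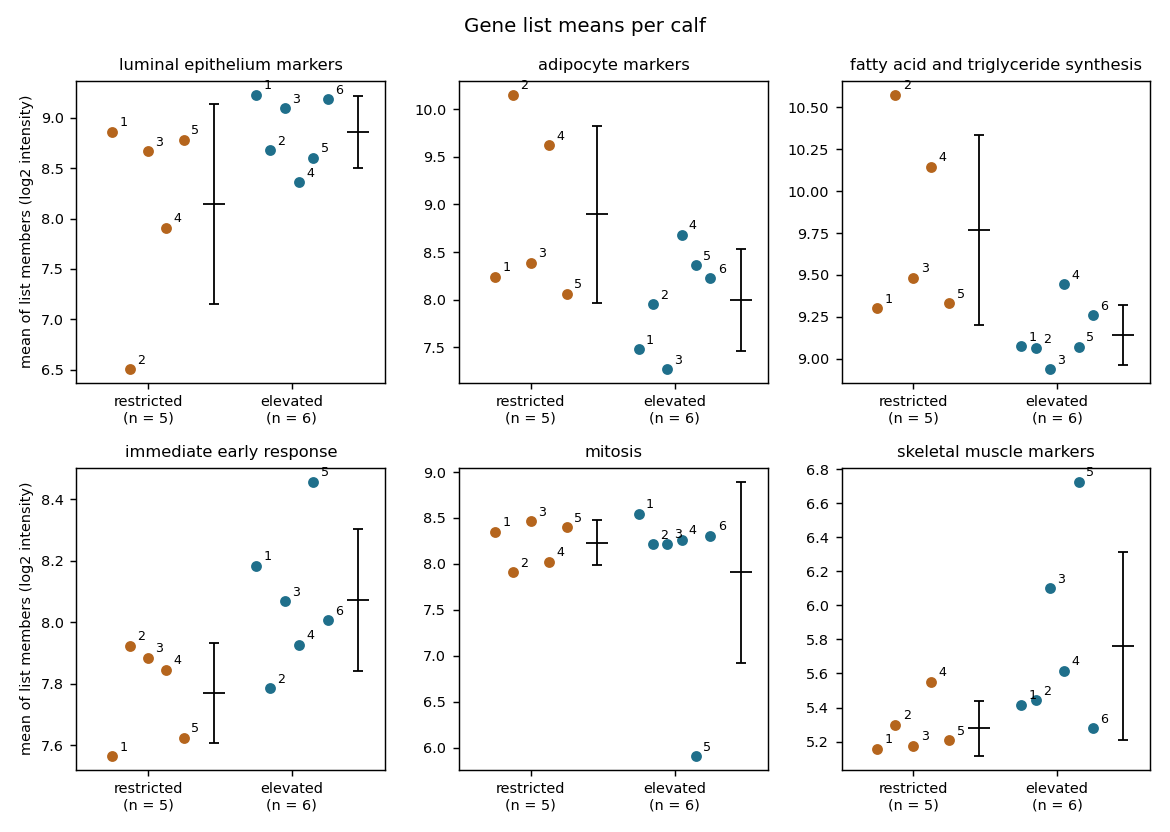
Mean log2 intensity of the members of 6 gene lists (y axis) in each restricted (n = 5) and elevated (n = 6) calf; points carry the calf's number, and the bar with whiskers is the group mean ± SD. Restricted 2 and restricted 4 hold the highest adipocyte means (10.15 and 9.62), and elevated 5 has a mitosis mean of 5.91, below every other calf.

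The remaining lists did not pass camera in the full comparison, and their small means shifted with single calves. Cholesterol synthesis genes differed by 0.021 (adjusted p = 0.237), and SREBF2, their main transcriptional activator, by 0.45 ± 0.09 (SE), past the threshold adjusted over the list alone. Macrophage markers differed by -0.088 (adjusted p = 0.310), with VSIG4 at -0.82 ± 0.19 (SE) the 1 member past the threshold adjusted over the list alone. Schwann cell and nerve markers differed by 0.20 (adjusted p = 0.0978), with the myelin gene MBP at 0.56 ± 0.15 (SE) the 1 such member. The mean differences were 0.039 for insulin and FOXO targets, -0.037 for amino acid response genes, 0.048 for the unfolded protein response, 0.035 for mRNA splicing, -0.0076 for ribosome biogenesis and 0.10 for interferon response genes. Over left-out calves the interferon mean ran from 0.0048 to 0.27 and passed in 2 of 11, and the splicing mean from 0.013 to 0.061 and passed in 3. In the amino acid response list, ATF5 differed by -1.01 and the cationic amino acid transporter gene SLC7A1 by 0.36. ATF5 stood at 11.10 in restricted 2 and 10.50 in restricted 4, against 9.24 to 9.52 in the other restricted calves. Markers of other cell types differed by -0.063 (endothelium), 0.047 (T and B lymphocytes), 0.016 (smooth muscle and pericytes), -0.22 (red blood cells) and -0.068 (keratinocytes), with camera adjusted p of 0.672, 0.672, 0.719, 0.225 and 0.712.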

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

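The tests on elevated 5 and on adipocyte tissue were chosen after the results were seen. In each group, the highest or lowest calf was set against the gap to its neighbour by Dixon's ratio, for 28 list means and the genes named in the text. Of 214 groups, 15 had an outlying calf, where chance alone gives about 10.7 (1 in 20), and 9 of the 15 were elevated 5.

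Elevated 5 lay below the other elevated calves in cell division genes. Its mitosis mean was 5.91 (others 8.21 to 8.55) and its DNA replication mean 7.03 (others 7.90 to 8.18). It was likewise lowest in MKI67 (6.13), TOP2A (6.36), CENPA (6.07), DDC (4.32), S100A9 (4.76), the macrophage list (7.78) and the hormone and growth factor list (8.56). The mitosis genes of this calf differed from the mean of the other 5 elevated calves by -2.40 on the log2 scale, with 41 of 41 lower and 40 by over 2-fold. Dilution by another tissue would lower epithelial genes alike, but its luminal markers differed by -0.30 (SD of the other elevated calves 0.38), far from the mitosis gap. Its basal markers differed by -0.35, although the basal keratin KRT5 was lower, at 8.08 against 9.25 to 10.61 in the other elevated calves. A general loss of array or RNA quality could not be excluded: this array had the lowest mean correlation with the others (0.970, next 0.971 in restricted 2) and the lowest array weight (0.412, next 0.477 in restricted 2). The gap in correlation is smaller than the spread of the other arrays (SD 0.00348), and a calf with other biology would give low values too. Its skeletal muscle mean lay 1.16 and its endothelial mean 0.74 above the others. No biological explanation was tested, since the design gives none within a group, and a lower share of dividing cells in this calf or sampling site stays open.

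The adipocyte and luminal differences rest largely on restricted 2 and restricted 4. More fat pad tissue in some restricted samples is a candidate explanation. With the adipocyte mean as a covariate the luminal difference went from 0.71 to -0.053 (SE 0.26), which leaves room for a difference of either sign. Lower lipid synthesis transcripts beyond the adipocyte share could not be told apart from that: the fatty acid list went from -0.63 to -0.17 (SE 0.11) with the covariate, between 1 and 2 SE below 0. Camera kept its call there (adjusted p = 0.0032), but at its preset correlation it takes members as nearly independent and does not count the spread of the list mean between calves. Tissue taken with the sample and a gland that truly held more fat under restricted feeding give the same values here, so the feeding level stays an open explanation.

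Other outlying values were lactoferrin, LTF, in restricted 2 (7.67, others 10.11 to 10.67), ACTN2 in restricted 4 (5.11, highest), SLITRK6 (9.15, lowest) and LAMB1 (11.43, highest) in elevated 4, LALBA in elevated 2 (3.09, highest) and UQCRH in elevated 3 (7.42, lowest).

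Regrouping the calves tested the counts themselves. Of 100 splits into 6 and 5 drawn from the 462, the real one included, 2 gave at least 2 probe sets past the adjusted threshold. That share lies under 0.05. It is an estimate from drawn splits, for a small count that moved with single calves, so chance is not firmly excluded. The highest other split gave 109. That split set elevated 2, 4 and 5 with restricted 2 and 4 against the rest. These calves had the highest scores on the principal component with 26% of the variance (-3.02 to 62.3, the rest -27.8 to -10.95). A split along that component thus calls more probe sets than the diet contrast. At an unadjusted p under 0.05, 5 splits gave at least the real 2750 probe sets (highest other 4481), and chance was not excluded. For gene lists, 74 splits gave at least the real 10 (highest other 19), so chance was not excluded for the number of lists that camera calls at its preset correlation.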

How the results depend on the processing

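Fits without restricted 2, restricted 4 or elevated 5 together were chosen after seeing the data. The count of 2 probe sets was 1 with only probe sets of 1 gene, 4 with array weights, 0 with Welch's test, 9 with the luminal mean as a covariate, 25 without restricted 2 and 4, 15 without those and elevated 5, and 0 to 12 when each calf was left out. Apart from the block below, it stayed within 1.5 times under the other alternatives. FMN1 passed in 18 of 25 alternatives (log2 change -1.23 to -1.10, adjusted p 0.00983 to 0.193). The count of 10 lists was 0 with an estimated correlation, 0 with fry (3 unadjusted) and 6 without restricted 2 and 4 (4 of them shared); it was 8 to 15 when each calf was left out. Without restricted 2 and 4 the list differences themselves shrank, for luminal markers from 0.71 to 0.088 and for adipocyte markers from -0.90 to -0.24. The causes of the other shifts in these counts were not tested.

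Directions turned for these list differences. With array weights they were -0.0018 (basal), 0.020 (DNA replication), 0.018 (ribosome biogenesis), -0.011 (insulin and FOXO targets) and -0.018 (smooth muscle). With the adipocyte mean as a covariate they were -0.053 (luminal), -0.37 (basal), 0.039 (ribosome biogenesis), -0.0067 (splicing), -0.025 (hormone signalling), 0.0034 (amino acid response), 0.049 (beta oxidation), 0.22 (endothelial), -0.17 (T and B lymphocytes) and -0.029 (interferon). Without restricted 2 and 4 they were -0.29 (basal), 0.014 (ribosome biogenesis), -0.0074 (splicing), -0.0081 (hormone signalling), 0.016 (amino acid response), 0.018 (beta oxidation), 0.13 (endothelial) and -0.16 (T and B lymphocytes). Also without elevated 5 they were -0.23 (basal), 3.5e-05 (DNA replication), 0.023 (ribosome biogenesis), -0.0020 (insulin and FOXO targets), 0.029 (amino acid response), 0.017 (oxidative phosphorylation), 0.020 (beta oxidation), 0.0037 (endothelial), -0.084 (T and B lymphocytes), 0.087 (macrophages), -0.0014 (smooth muscle) and -0.025 (Schwann cells). For matrix with the covariate (-0.019) and oxidative phosphorylation without restricted 2 and 4 (-0.00421), the mean kept its sign but camera's direction turned. Of these, camera called 5 in the new direction: basal with the covariate (adjusted p 0.00729), without restricted 2 and 4 (0.0412) and also without elevated 5 (0.0137), endothelial with the covariate (0.00298), and T and B lymphocytes without restricted 2 and 4 (0.0412).

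With all calves kept, calls were lost with array weights for mitosis (-0.13), oxidative phosphorylation (-0.056) and beta oxidation (-0.11). With the adipocyte covariate they were lost for oxidative phosphorylation (-0.011) and ribosomal proteins (0.028). The luminal (-0.053), matrix (-0.019) and beta oxidation (0.049) lists, given above as turned, also lost their calls with that covariate. Calls were gained in the same direction by 9 lists. Leaving out each calf, splicing passed in 3 of 11 (0.013 to 0.061), interferon in 2 (0.0048 to 0.27), Schwann cells in 2 (0.12 to 0.26), the unfolded protein response in 1 (0.024 to 0.087), and endothelial and macrophage markers in 1 each. The others were milk proteins with the dimmest probe sets left out (0.59), DNA replication with the adipocyte covariate (-0.21), and cholesterol and the unfolded protein response with array weights (0.098 and 0.072) and without restricted 2, restricted 4 and elevated 5 (0.11 and 0.073). When each calf was left out, 3 uncalled lists kept their direction but also moved by over 1.5 times. They were hormone signalling (0.019 to 0.14), red blood cells (-0.29 to -0.13) and keratinocytes (-0.12 to -0.018). Hormone signalling turned under the other alternatives given above.

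Leaving out each calf gave ranges across 0 for 11 lists. They were -0.12 to 0.11 for DNA replication and -0.45 to 0.078 for mitosis, both turned by elevated 5 and then called in the new direction. The others were -0.15 to 0.24 (basal), -0.027 to 0.074 (cholesterol), -0.041 to 0.031 (ribosome biogenesis), -0.027 to 0.087 (insulin and FOXO targets), -0.056 to 0.0013 (amino acid response), -0.19 to 0.032 (endothelial), -0.039 to 0.12 (T and B lymphocytes), -0.15 to 0.025 (macrophages) and -0.021 to 0.049 (smooth muscle). Over all lists, 453 of 559 alternatives kept the direction and side of the threshold. In the same direction, 36 lost the call and 16 gained one, and 54 turned in 19 lists, with or without a change of call. For the 144 named genes, 2136 of 2160 kept direction and side, 5 lost a call (all FMN1), 7 gained one and 12 turned, none of these past the threshold. Named genes were run under fewer alternatives than the 25 given for FMN1 above, so its lost calls differ between the tallies. Leaving out 1 calf turned 43 of the genes or moved them by over 1.5 times, 21 through restricted 2 and 15 through elevated 5; FMN1 was not among them. The 12 were in 5 genes, with ranges over left-out calves of -0.21 to 0.0051 (IGFBP3), -0.057 to 0.034 (LALBA), -0.36 to 0.54 (KRT5), -0.45 to 0.19 (MKI67) and -0.70 to 0.020 (TOP2A); LALBA was also 0.0062 with the block.

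Replicate numbers 1 to 5 occur in both groups and gave no clear sign of pairing. Deviations of same-numbered calves correlated at -0.15 to 0.21, against a mean of -0.018 for other pairs. Only 1 of 5 elevated calves correlated best with its own number. A shared day or batch is not excluded by these values. With the replicate number as a block, 0 probe sets and 9 lists passed, and the ribosomal protein list lost its call (0.047, adjusted p 0.0508). Signal over background is not given per probe set, so whether dim genes such as LALBA were detected is not known.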

Other observations

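The neutrophil test was fixed before its result was seen, the test with the adipocyte covariate after. The cathelicidin genes CATHL1, CATHL2 and CATHL3, which encode antimicrobial peptides, had lower means in elevated calves. They were picked after their values were seen, and the family was not tested as a list. CATHL1 averaged 4.24 ± 0.47 (SD, n = 6) in elevated and 6.05 ± 1.20 (SD, n = 5) in restricted calves, a log2 difference of -1.80 ± 0.47 (SE; limma adjusted p = 0.287). CATHL3 differed by -1.95 ± 0.44 (SE; adjusted p = 0.236) and CATHL2 by -1.05 ± 0.28 (SE; adjusted p = 0.293). None passed in the full comparison, and values of CATHL1 and CATHL2 overlapped between the groups. The other 2 genes with a cathelicidin symbol differed by -0.21 (CATHL5) and -0.098 (CATHL6). Without restricted 2 and restricted 4, left out after seeing the data, CATHL1 (-2.64, adjusted p = 0.0259), CATHL2 (-1.56, adjusted p = 0.0128) and CATHL3 (-2.68, adjusted p = 0.0272) all passed. The calves left out held the lowest restricted values of each of these genes, so leaving them out widens the gap and the passes are not separate support. Restricted 1, 3 and 5 had CATHL1 values of 7.40, 6.53 and 6.71, against 4.51 in restricted 2 and 5.07 in restricted 4. PIGR and LTF, defence genes given with the milk proteins, had differences of the opposite sign, 2.09 and 1.15 (0.60 for LTF without restricted 2).

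More neutrophils in restricted samples is a candidate explanation, since these cells store cathelicidins. Of 26 neutrophil markers listed beforehand, 19 were measured, 8 higher and 11 lower in elevated calves, with a median difference of -0.073 (exact permutation p of the mean 0.877). S100A12, the brightest of the 3 S100 genes among them, differed by 0.025 (7.25 against 7.23), S100A8 by -0.59 (5.20 against 5.78) and S100A9 by -0.18 (5.99 against 6.16), all short of the cathelicidin differences. Other markers went both ways, with BPI at -0.53, MMP9 at -0.40 and MPO at -0.23, against HP at 0.74, PGLYRP1 at 0.61 and CD177 at 0.38. That argues against more neutrophils across the restricted group as a whole. The markers were not compared in restricted 1, 3 and 5 alone, which held the highest cathelicidin values, so a neutrophil source in those calves is not excluded. Of the 19, 5 lay above the median level of all probe sets, and 1 (ITGAM) is also on the macrophage list. More fat pad tissue in some restricted samples is argued against too: with the adipocyte mean as a covariate, the mean difference of the 3 genes went from -1.60 to -2.24 (SE 0.34). This follows from the order of the calves, since restricted 2 and 4, with the highest adipocyte means, had the lowest restricted values of all 3 genes. Shared probe sequence among these closely related genes was not tested, so they may be fewer than 3 independent readings. A response to the feeding level stays open as a hypothesis.

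The uncharacterised locus LOC785756, singled out after its values were seen, differed by 3.23 ± 0.52 (SE; limma adjusted p = 0.135), at 11.84 in elevated and 8.61 in restricted calves, with no overlap between the groups.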
